A study of Mus musculus with 10 samples.

How the data were processed

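RNA from 10 whole mammary tumours was analysed, 5 from doxycycline-treated hosts and 5 from hosts on sugar water, all grown from Wap-Myc mammary epithelial cells transduced with an inducible hepsin construct in the FVB background. Per the labels' protocols, cells were transduced at a multiplicity of 10 and transplanted into hosts aged 3 weeks, doxycycline began 3 days after transplantation, and Myc was induced from 8 weeks of age. Total RNA was depleted of ribosomal RNA and made into directional libraries, which were read single-end to 75 bp on a NextSeq instrument, per the labels' protocols. The values deposited by the authors were whole-number counts of reads per Ensembl gene, not normalised, for 55335 genes, of which 23154 had no count in any tumour. The submitters' processing notes name bcl2fastq, Trimmomatic, STAR 2.6.0c, featureCounts, DESeq2 and the build GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here. Counts over the tumours summed to 418344 on Xist and 55 on its antisense partner Tsix, so the strand was in effect kept apart there.

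Gene symbols came from a name table (55154 of 55335 identifiers matched without their version), and coordinates from the GENCODE M21 annotation of GRCm38. Groups and replicate numbers were taken from the sample titles. Within groups, the 20 pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom 6.76 to 41.9 over genes with at least 10 counts, correlation 0.956 to 0.991), so each counted as a separate sample. Total counts ran from 14256948 to 39358457, and DOX 3 alone exceeded 20469533. Ribosomal and abundant non-coding loci (rRNA biotypes, Gm26917, Gm42418 and Gm23935) took 24.5 to 33.3% of counts, 29.3 ± 3.61% in controls and 27.3 ± 2.30% with doxycycline (SD, n = 5, exact permutation p = 0.317). The first principal component held 31.0% of the variance, with no_DOX 4 and DOX 5 at its ends, and did not separate the groups (exact permutation p = 0.151).

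Differences between groups were tested with edgeR 4.0.16 (TMM scaling, filterByExpr with its minimum count of 10 and minimum total of 15, quasi-likelihood test without the robust option, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, without a block. The filter left 16167 genes. CPM are counts scaled to library size with TMM factors and given as mean ± SD. The standard error of a log2 fold change was its size divided by the square root of F. Hpn was tested with a two-sided exact permutation test of log2(CPM + 1), for which 5 against 5 tumours allow a smallest p of 0.00794. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided, adjusted over lists). Of 27 lists written before the data were examined, 24 had at least 5 tested members. The skeletal muscle, B and plasma cell and erythroid lists had 3, 3 and 2 tested members, with median log2 fold changes of 0.06, 1.12 and 0.93, and were not tested. The level of a list is the mean of its members' log2 CPM after centring each gene on the 10 tumours, and levels were compared by exact two-sided permutation tests.

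The named genes followed a rule set before the data were examined. They were Hpn, the 8 genes in each direction with the smallest p where none passed (mean of at least 1 CPM in a group, predicted genes and pseudogenes left out), and 2 members of each tested list with the smallest p. Of the TGF-beta target list, 1 member that entered the list tests is not reported here on its own. Others are said in the text to have been named after their values were seen. Alternatives were DESeq2 1.42.0, limma voom with sample weights, other scalings (DESeq2 size factors, library size only), no low-count filter, at least 1 CPM in 5 libraries, a robust fit, a threshold of 0.1, a replicate block, a pseudocount of 0.1, an estimated inter-gene correlation, fry, and each library left out in turn. Counts were simulated for independent genes with the means, depths and estimated per-gene spread of these tumours, without repeats. On them edgeR recovered 35% of 200 genes changed 1.5-fold, 76% changed 2-fold and 91% changed 4-fold, and made 0 calls when no gene changed. Genes in the real tumours vary together, so these shares need not hold for the real counts. In simulated lists of independent genes camera called 0 of 24 lists when nothing changed and called the TGF-beta targets at a 1.3-fold change. Regroupings of the tumours were counted over 100 of the 126 possible splits into 5 and 5, the real split included.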

Results

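Gene expression was measured by RNA sequencing in 10 mouse mammary tumours of the Wap-Myc model, in which the Wap promoter, active in the mammary gland during pregnancy and lactation, drives the Myc oncogene. Mammary epithelial cells carrying the transgene had been transduced with a doxycycline-inducible lentiviral construct for hepsin, a type II transmembrane serine protease of epithelial cells, and transplanted into mammary fat pads. The hosts of 5 tumours (named DOX) drank doxycycline at 2 mg/ml in 5% sucrose, and those of the other 5 (no_DOX) drank sugar water. Tumours were taken at a diameter of 1 cm after Myc induction by 2 pregnancies, and whole-tumour RNA was sequenced, so stromal and immune cells contributed to it. Total counts per tumour lay between 14256948 and 20469533, except in DOX 3, which had 39358457. The comparison asked which genes differed when hepsin was induced, with TGF-beta signaling named in the title of the series. All tumours carried the construct, so doxycycline itself and hepsin induction could not be separated. The labels do not say whether each tumour came from its own host, so p-values measure the spread between these tumours.

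With doxycycline, tumours had less type I and type III collagen transcript. Col1a1, Col1a2 and Col3a1 averaged 0.450, 0.451 and 0.460 of their control levels, the last named after its values were seen. In the integrated stress response list, Psat1, Shmt2, Asns and Aldh18a1 were lower, with log2 fold changes of -0.33 to -0.57, and Sesn2 was higher (0.68), while camera, a test of whole lists, did not place the list apart (adjusted p = 0.157). Mfge8, a secreted glycoprotein of the milk fat globule, was 1.72-fold higher. These genes passed the test adjusted over the list alone, in gene lists fixed in advance, and none passed edgeR's test over all 16167 genes. That adjustment was made within each list, with no correction for the number of lists, so some passes can arise by chance. TGF-beta target genes leaned upwards, 22 of 28 being higher, and all 26 cell cycle genes were lower, by amounts that a test of their shared level over tumours did not separate from the spread. The TGF-beta target list shares no gene with the list of fibrillar collagens and matrix genes, so the lower collagen genes are not counted in it.

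Over all genes, edgeR's quasi-likelihood test called 0 genes at an adjusted p under 0.05, the smallest adjusted p being 0.140. At an unadjusted p under 0.05 there were 2592 genes, 1326 higher and 1266 lower with doxycycline, where 808 would be reached by chance. Scaling by library size only gave 2307 genes, 67.8% of them higher against 51.2%, and leaving out both no_DOX 4 and DOX 5 gave 1384 genes. DESeq2 called 322 genes (201 higher and 121 lower) on the same counts, and limma voom with sample weights called 775 (342 higher and 433 lower). Voom gave DOX 3, the deepest library, a weight of 4.65. The other DOX tumours had weights from 0.465 (DOX 2) to 1.04 (DOX 1), so voom's calls, here and below, lean heavily on DOX 3. DESeq2 and voom shared 240 calls, all 240 in the same direction, and all 322 genes called by DESeq2 had an unadjusted p under 0.05 with edgeR. The tools fit the same tumours and contrast, so such agreement is largely built in and adds no independent evidence. In 476 genes (2.94%) every DOX tumour lay on the same side of every control tumour, where chance gives 0.794% on average. Genes vary together, and this count was not made for other splits of the tumours. How far chance alone could raise it is therefore not known. Leaving out no_DOX 3 gave 37 calls with edgeR (8 higher and 29 lower), Mcm6, Wdr76, Bex1 and Mdc1 among the lower ones, and leaving out DOX 2 gave 2.

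Mouse Hpn (ENSMUSG00000001249.14, GRCm38 chromosome 7, 31098725 to 31115290, minus strand, protein coding) was read at 21.7 ± 4.69 CPM (SD, n = 5) in control tumours and 31.7 ± 8.55 CPM (SD, n = 5) in DOX tumours, on 245 to 1012 counts per tumour. The mean log2 level was higher with doxycycline by 0.52, or 1.44-fold, with a two-sided exact permutation p of 0.0159, and 4 of 5 DOX tumours lay above the highest control. In edgeR's test over all genes the log2 fold change of Hpn was 0.55 (SE 0.20, adjusted p = 0.247). Leaving out no_DOX 4, the tumour with the lowest value (14.2 CPM), reduced the difference to 0.38 with an exact permutation p of 0.0556, and with voom's sample weights it was 0.32 (limma p = 0.0594). The sources used here do not state which species' hepsin the construct encodes, and reads from a human sequence need not be counted on the mouse gene, so it is open whether these counts include the induced transcript.

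**Figure D1:**
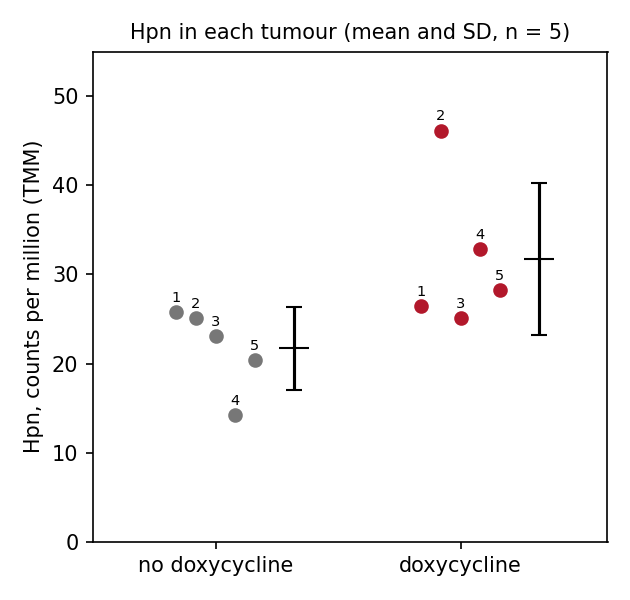
TMM-scaled CPM of Hpn (vertical axis, from 0) in each tumour, by group, with replicate numbers beside the points and the mean and SD (n = 5) as bars. DOX 2 had the highest value, 46.1 CPM, and no_DOX 4 the lowest, 14.2 CPM.

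Of 28 TGF-beta target genes, 22 were higher and 6 lower in DOX tumours, with a median log2 fold change of 0.25. Limma's camera test with a preset correlation of 0.01 placed the list above other genes (adjusted p = 0.00129), and with an estimated correlation the call was lost (adjusted p = 0.863 with an estimated correlation). No member passed edgeR's test over all genes or adjusted over the list alone (0 genes each), and 7 members, all higher, had an unadjusted p under 0.05. Among these, Ski, a nuclear repressor of SMAD signaling, was at 171 ± 17.6 CPM in controls and 209 ± 13.6 CPM with doxycycline (SD, n = 5), above every control in 5 of 5 DOX tumours, with an edgeR adjusted p of 0.199. Pdgfb, encoding a growth factor for mesenchymal cells, was at 19.4 ± 5.86 and 33.2 ± 8.83 CPM (edgeR adjusted p = 0.215). Ltbp2 and Ccn2, named after their values were seen, had log2 fold changes of 0.99 (SE 0.31) and 0.88 (SE 0.33). DESeq2 called Ski, Pdgfb and Ltbp2 as higher, and voom called Ski, Pdgfb and also Smad6, named after its values were seen. The inhibitor Smad7, also named after its values were seen, had a log2 fold change of 0.44 (SE 0.19). The mean level of the list was -0.12 ± 0.35 in controls and 0.12 ± 0.27 with doxycycline on a centred log2 scale (SD, n = 5), a difference with an exact permutation p of 0.238. No_DOX 2, no_DOX 4 and DOX 2 had the lowest levels (-0.34, -0.62 and -0.28).

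The basal and myoepithelial markers largely moved with the TGF-beta targets, though not in DOX 4 (-0.92, against 0.08 for the targets). All 13 were higher in DOX tumours, with a median log2 fold change of 0.60, but the list did not pass (camera adjusted p = 0.0740). Its lowest levels were in no_DOX 4 (-1.39) and no_DOX 2 (-1.04), followed by DOX 4 and DOX 2 (-0.59). Krt5 and Krt14, named after their values were seen, had log2 fold changes of 0.82 (SE 0.97) and 0.26 (SE 0.74). Myh11, a smooth muscle myosin, was at 5.28 ± 1.70 and 10.2 ± 4.03 CPM, and Krt15 at 1.43 ± 0.653 and 4.23 ± 2.97 CPM (SD, n = 5), with edgeR adjusted p of 0.235 and 0.245, and voom called Myh11 as higher. Of 26 genes for TGF-beta pathway components, 20 were higher and 6 lower (median log2 fold change 0.13, camera adjusted p = 0.0740). The ligand gene Tgfb1 was at 28.5 ± 3.67 CPM in controls and 40.8 ± 9.69 CPM with doxycycline, above every control in 4 of 5 DOX tumours (edgeR adjusted p = 0.230). Smad5, a receptor-regulated SMAD of the BMP branch, was at 102 ± 6.26 and 113 ± 5.40 CPM (edgeR adjusted p = 0.264).

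**Figure D2:**
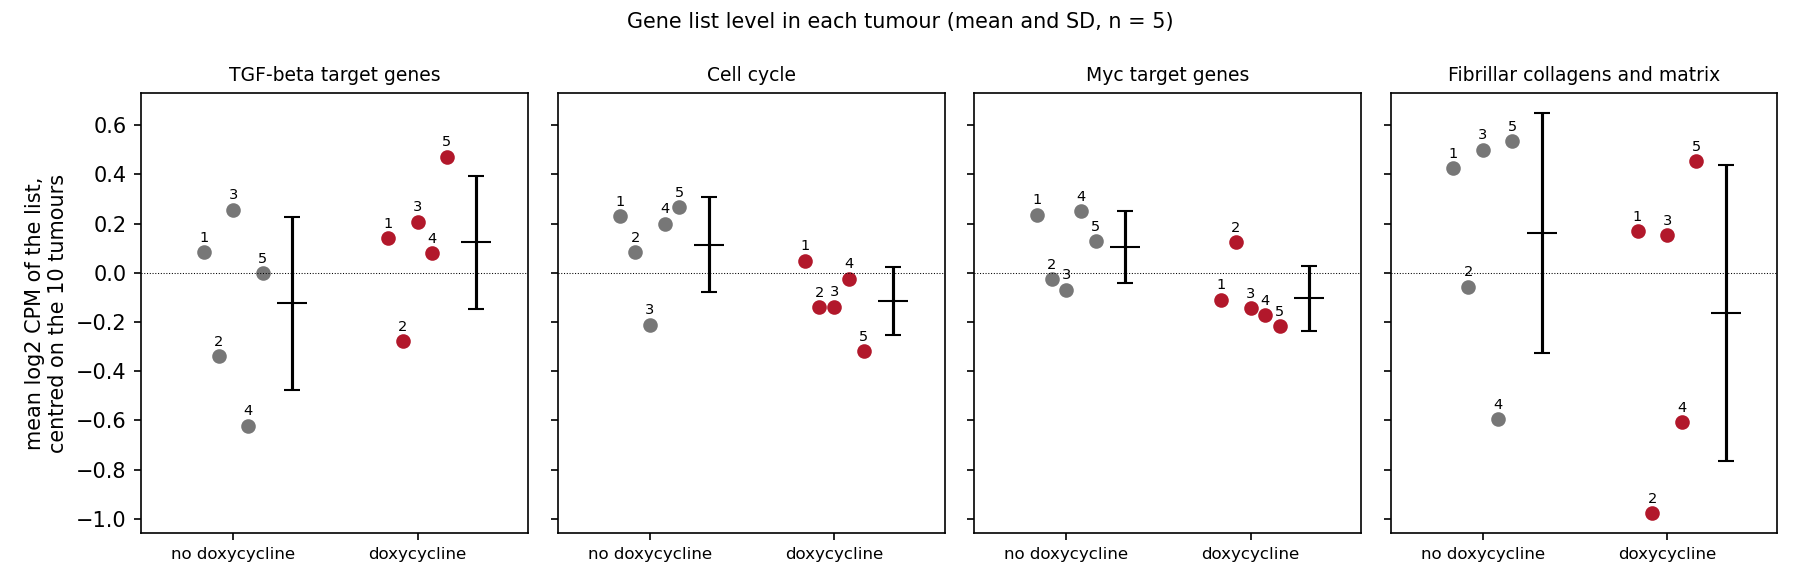
Mean log2 CPM of 4 gene lists, centred on the 10 tumours (vertical axis), in each tumour by group, with replicate numbers beside the points and the mean and SD (n = 5) as bars. The groups overlap in every list; TGF-beta target genes run from -0.62 in no_DOX 4 to 0.47 in DOX 5.

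Fibrillar collagens and matrix genes gave a mixed picture in which 15 of 23 members were lower. Col1a1 (GRCm38 chromosome 11, 94936224 to 94953042) fell from 1576 ± 465 to 709 ± 238 CPM and Col1a2 (chromosome 6, 4504814 to 4541544) from 930.5 ± 255 to 419.7 ± 134 CPM (SD, n = 5). Every DOX tumour was below every control for both genes. Col3a1, the type III collagen chain, named after its values were seen, fell from 503 ± 169.8 to 231 ± 76.1 CPM, below every control in 4 of 5 DOX tumours. For these 3 genes edgeR's p adjusted over the list alone was 0.0138, 0.0138 and 0.0150, against 0.196 over all genes, and DESeq2 and voom called all 3. Fn1, encoding fibronectin and named after its values were seen, went the other way without passing, at 851 ± 301 and 1172 ± 531 CPM (edgeR adjusted p = 0.543). The list as a whole had a camera adjusted p of 0.0419 and a median log2 fold change of -0.23, and an adjusted p = 0.863 with an estimated correlation. Without any of no_DOX 1, no_DOX 3, no_DOX 5, DOX 2 or DOX 4 the camera call was also lost, at adjusted p of 0.116, 0.200, 0.146, 0.351 and 0.130.

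**Figure D3:**
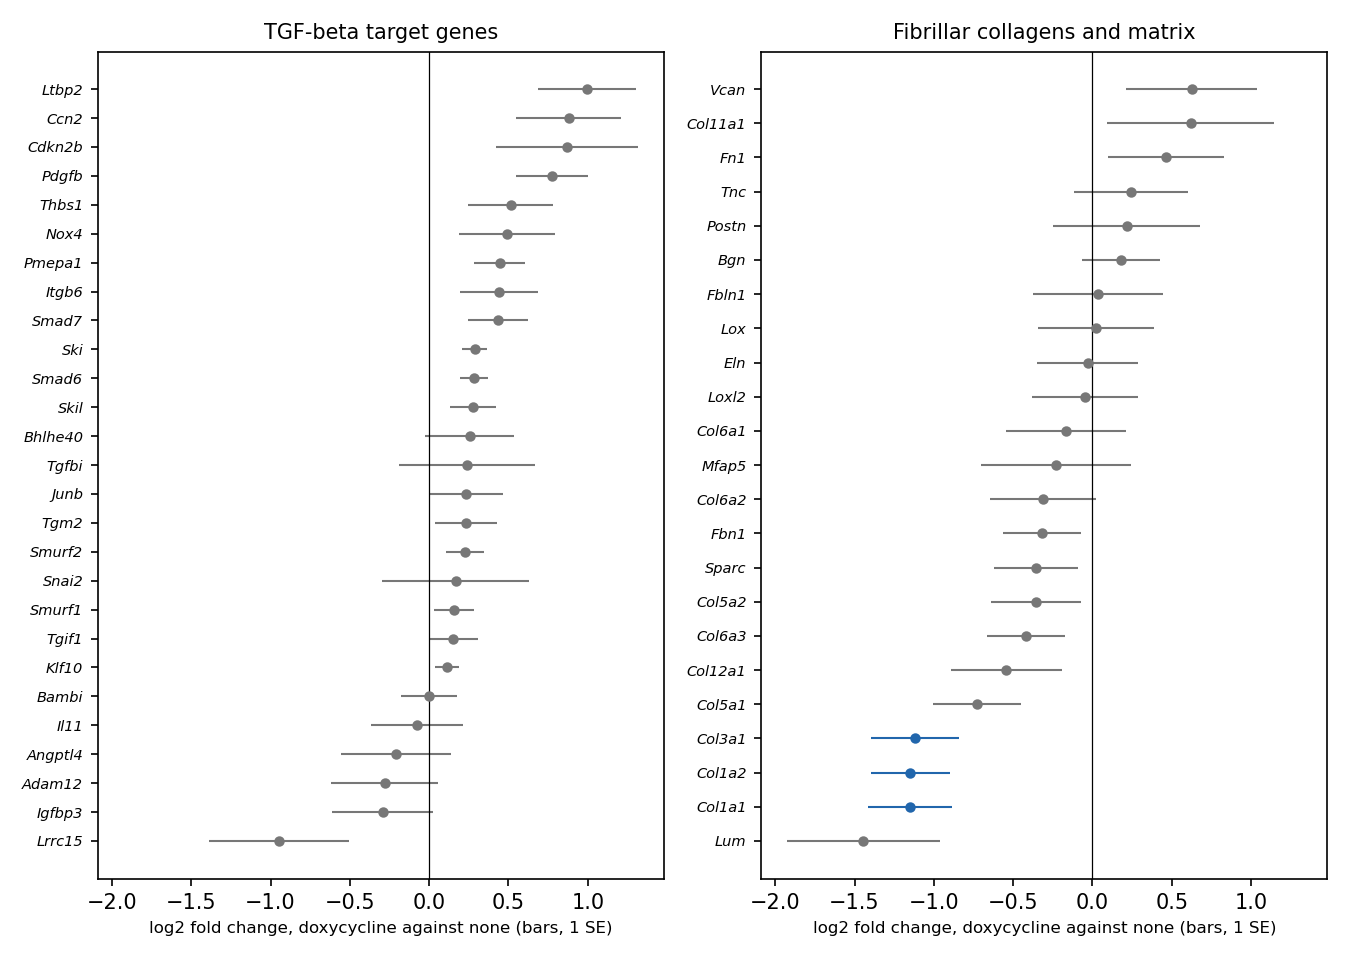
Log2 fold changes of members of 2 gene lists (horizontal axis, doxycycline against none, bars 1 SE from edgeR), ordered by size, with blue for genes past adjusted p 0.05 over the list alone and grey for the others. Col1a1, Col1a2 and Col3a1 are blue at -1.15, -1.15 and -1.12, and no TGF-beta target gene shown is blue.

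Proliferation and growth genes were lower by small amounts. All 26 cell cycle genes were lower with doxycycline, with a median log2 fold change of -0.23 and 14 of them at an unadjusted p under 0.05. Camera gave an adjusted p of 1.59e-07, lost at an adjusted p = 0.863 with an estimated correlation, and the mean level of the list differed by -0.23 with an exact permutation p of 0.0794. No member passed with edgeR adjusted over the list alone (0 genes) or over all genes. Mcm6, of the replicative helicase, was at 157 ± 23.2 and 122 ± 5.87 CPM, and Bub1b, of the mitotic checkpoint, at 145 ± 16.5 and 113 ± 12.9 CPM (SD, n = 5), with edgeR adjusted p of 0.196 and 0.213. DESeq2 called Mcm6 as lower (adjusted p = 0.0461), and so did edgeR without no_DOX 3 (adjusted p = 0.0311). Voom called Mcm6 and Bub1b (adjusted p of 0.0341 and 0.0352) as lower, and also Mcm4, Mcm5, Cdc20 and Top2a, named after their values were seen. Of 24 Myc target genes, 22 were lower (median -0.21, camera adjusted p = 9.76e-07, and adjusted p = 0.863 with an estimated correlation), and the mean level differed by -0.21 (exact permutation p = 0.0476, adjusted over 24 lists 0.749). Shmt2, the mitochondrial serine hydroxymethyltransferase, was the 1 member that passed adjusted over the list alone and fell from 171 ± 21.1 to 127 ± 11 CPM. Ncl, encoding nucleolin, was at 1554 ± 163 and 1258 ± 133 CPM (edgeR adjusted p = 0.224), and voom called it as lower. Myc itself, named after its values were seen, was at 433 ± 100.4 and 377 ± 88.1 CPM, with an edgeR log2 fold change of -0.20 (SE 0.18) and an adjusted p of 0.582.

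Integrated stress response genes moved in both directions. Of 19 members tested, 4 fell and 1 rose adjusted over the list alone, and 0 passed over all genes with edgeR. Psat1, of the phosphorylated serine pathway, fell from 169 ± 12.9 to 132 ± 8.38 CPM and was below every control in 5 of 5 DOX tumours. Asns (asparagine synthetase) fell from 66.5 ± 11.6 to 44.7 ± 7.70 CPM, and Aldh18a1, of proline synthesis, from 135 ± 13.7 to 108 ± 9.38 CPM (SD, n = 5). Sesn2, an inhibitor of mTORC1 signaling, rose from 15.3 ± 4.68 to 24.5 ± 4.95 CPM. The last 3 were named after their values were seen. DESeq2 and voom called Psat1, Shmt2, Asns and Aldh18a1 as lower, and neither called Sesn2. Camera did not place the list apart (adjusted p = 0.157, and 0.863 with an estimated correlation), while fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.00251. The mixed test asks about change against none, not against other genes, and was not run over the splits of the tumours. That test also passed for endothelium and pericyte markers (adjusted p = 0.0163), of which 6 were higher and 10 lower. Vwf was at 3.94 ± 1.33 and 11.8 ± 9.89 CPM and Kdr at 21.6 ± 3.04 and 17.3 ± 1.40 CPM (SD, n = 5), and DESeq2, but not voom, called Vwf as higher.

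Among mammary epithelial genes, Mfge8 rose from 312 ± 78.5 to 538 ± 41.2 CPM (SD, n = 5; p adjusted over the list alone 0.00477, edgeR adjusted p over all genes 0.196). Of the 13 milk and secretory genes, 11 were lower, among them Elf5, a regulator of alveolar differentiation, at 126 ± 23.0 and 88.6 ± 19.1 CPM, and the list did not pass (median log2 fold change -0.51, camera adjusted p = 0.170). Luminal markers were higher in 10 of 15 genes (median 0.23, adjusted p = 0.157). Prom1 was at 21.2 ± 7.14 and 35.2 ± 3.85 CPM, and Foxa1 at 5.29 ± 4.55 and 25.2 ± 30.8 CPM, a range set by a few tumours. In the basement membrane list, 12 of 20 genes were higher (median 0.18, adjusted p = 0.281). Lama1 fell from 32.4 ± 8.98 to 18.6 ± 3.63 CPM, the 1 gene that passed adjusted over that list alone, and Lama5 was at 208 ± 67.8 and 362 ± 90.5 CPM (edgeR adjusted p = 0.221). Epithelial junction genes had a median of 0.04 (14 of 22 higher, adjusted p = 0.323). Pkp3 (plakophilin 3) was at 56.4 ± 10.5 and 79.5 ± 8.06 CPM, above every control in 5 of 5 DOX tumours (edgeR adjusted p = 0.196), and Cldn7 was at 36.1 ± 6.83 and 44.3 ± 5.37 CPM. DESeq2 called Mfge8, Prom1, Lama5 and Pkp3 as higher and Lama1 as lower, as did voom except for Lama5.

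**Figure D4:**
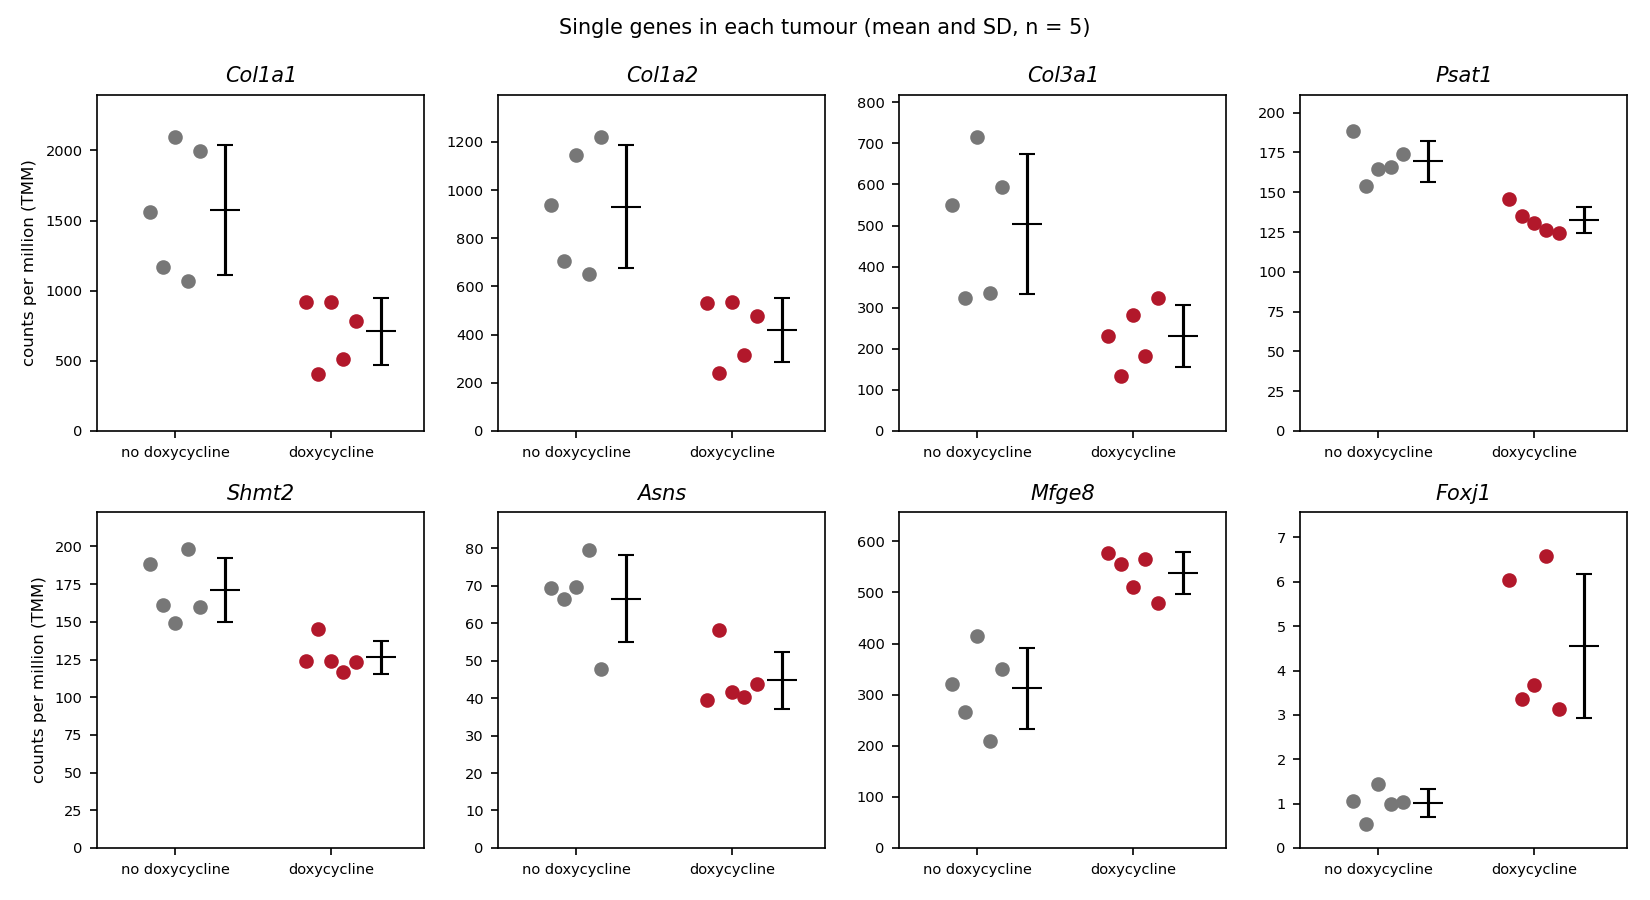
TMM-scaled CPM (vertical axes, from 0) of 8 genes in each tumour by group, with points for tumours and the mean and SD (n = 5) as bars. Col1a1, Col1a2, Psat1 and Shmt2 lie below every control in all 5 DOX tumours, Mfge8 and Foxj1 above.

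Genes of epithelial-mesenchymal transition were higher in 14 of 20 members (median 0.34, camera adjusted p = 0.526). Snai1, a repressor of E-cadherin, was at 11 ± 4.36 and 20.5 ± 5.30 CPM, above every control in 5 of 5 DOX tumours (edgeR adjusted p = 0.238), and Itgav at 104 ± 20.3 and 137 ± 45.4 CPM. Serine proteases and inhibitors related to hepsin were higher in 9 of 13 genes (median 0.19, adjusted p = 0.526), with Tmprss13 at 51.3 ± 10.7 and 37.1 ± 10.3 CPM and the inhibitor Spint1 at 30.3 ± 3.98 and 35.4 ± 3.66 CPM. HGF-MET signaling genes were higher in 9 of 14 (median 0.10, adjusted p = 0.373). The feedback inhibitor Spry4 was at 14.7 ± 5.62 and 26.3 ± 9.02 CPM, and the receptor gene Met at 70.9 ± 15.3 and 54.4 ± 9.90 CPM. Hypoxia and glycolysis genes were higher in 12 of 18 (median 0.05, adjusted p = 0.323), with Pfkfb4 at 3.67 ± 0.504 and 4.73 ± 0.833 CPM and Egln3 at 139.96 ± 57.3 and 209 ± 76.1 CPM. Interferon response genes were higher in 18 of 22 (median 0.38, adjusted p = 0.821), with Mx1 at 0.977 ± 0.597 and 1.88 ± 1.53 CPM and Isg15 at 1.27 ± 0.484 and 2.47 ± 2.73 CPM. The mean level of that list differed by only 0.03, with DOX 5 (1.71) and DOX 2 (0.82) above every control and DOX 1 (-0.66) and DOX 4 (-1.27) below. Its camera direction turned without no_DOX 2, no_DOX 4, DOX 2 or DOX 5 (adjusted p of 0.629, 0.934, 0.562 and 0.0343), and without both no_DOX 4 and DOX 5 (adjusted p = 0.00845). Mitochondrially encoded genes were lower in 6 of 7 (median -0.07, adjusted p = 0.436), with mt-Nd1 at 2469 ± 231 and 2246 ± 336 CPM and mt-Nd2 at 1285 ± 116 and 1204 ± 107 CPM.

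Apart from the mixed test of endothelium and pericyte markers, for which camera gave an adjusted p of 0.192, no list of stromal or immune markers passed, and the values here are from camera. Fibroblast markers were lower in 10 of 14 genes (median -0.10, camera adjusted p = 0.543), with Col14a1 at 33.4 ± 10.8 and 17.0 ± 9.10 CPM and Fbln2 at 215 ± 81.5 and 297 ± 29.7 CPM. Of 7 adipocyte markers 3 were higher and 4 lower (adjusted p = 0.568), and the median (-0.03) and the camera direction were below 0 while the mean (0.27) was above it. Lpl, lipoprotein lipase, fell from 41.7 ± 6.54 to 22.0 ± 6.85 CPM and passed adjusted over the list alone and with DESeq2 but not with voom, and Plin4 was at 0.638 ± 0.400 and 1.64 ± 1.20 CPM. Macrophage and monocyte markers were higher in 12 of 17 (median 0.05, adjusted p = 0.323), with Cd163 at 0.936 ± 0.627 and 2.45 ± 0.844 CPM and Mrc1 at 29.2 ± 8.71 and 45.8 ± 16.7 CPM, and voom called Cd163 as higher. T and NK cell markers were lower in 7 of 10 (median -0.25, adjusted p = 0.323), with Tcf7 at 6.05 ± 2.74 and 10.9 ± 2.90 CPM and Cd4 at 8.47 ± 4.16 and 6.07 ± 0.874 CPM, and voom called Tcf7 as higher. Neutrophil markers (4 of 7 higher, median 0.01, adjusted p = 0.769) included Cxcr2 at 0.558 ± 0.359 and 1.09 ± 0.765 CPM and Ltf at 2.99 ± 3.02 and 1.70 ± 0.975 CPM. Squamous markers (4 of 7 higher, median 0.07, adjusted p = 0.563) included Krt10 at 1.54 ± 1.44 and 6.76 ± 8.59 CPM and Calml3 at 2.55 ± 0.498 and 5.25 ± 5.08 CPM.

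The single genes with the smallest p-values did not pass edgeR's test over all genes, although their groups did not overlap, while DESeq2 and voom called all of those named here. Foxj1, the master regulator of motile ciliogenesis (ENSMUSG00000034227.7, GRCm38 chromosome 11, 116330704 to 116335399), was at 1.01 ± 0.321 CPM in controls and 4.56 ± 1.63 CPM with doxycycline (SD, n = 5), a log2 fold change of 2.17 (SE 0.30, edgeR adjusted p = 0.140). The kinase gene Sbk1 (21 ± 2.16 and 31.2 ± 3.16 CPM), Nanos1 (0.606 ± 0.109 and 1.34 ± 0.248 CPM) and Lmod1, encoding an actin nucleator of smooth muscle (2.95 ± 0.498 and 6.36 ± 1.57 CPM), were higher. So were Trabd2b, an inhibitor of Wnt ligands (4.06 ± 1.65 and 11.6 ± 2.89 CPM), the planar cell polarity gene Vangl2 (17.7 ± 1.91 and 25.4 ± 2.6 CPM) and the calcium channel gene Orai1 (9.89 ± 0.630 and 13.1 ± 0.651 CPM). Rnase2a was near the detection limit in controls, at 0.0603 ± 0.0609 CPM against 1.80 ± 1.6 CPM, and belongs to a family of similar ribonucleases among which reads could have been split. On the lower side, Itgbl1 was at 6.42 ± 2.20 and 1.22 ± 0.556 CPM (log2 fold change -2.36, SE 0.33, edgeR adjusted p = 0.140), and Wdr76 and Bex1 had the same adjusted p, with log2 fold changes of -0.50 and -1.87. Tube1, Dact1, Mdc1 and Igkv14-111 had log2 fold changes of -0.48, -1.30, -0.28 and -1.61, each with an edgeR adjusted p of 0.196, the last being an immunoglobulin segment with near-identical relatives.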

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

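The splits of the tumours for the count of 0 genes, for DESeq2 and for the cell cycle, Myc target and matrix lists were chosen after the results were seen, as were the lists of eosinophil, multiciliated, one-carbon and ribosome biogenesis genes reported here and under the other observations, and their tests with each tumour left out. Single tumours stood apart from the rest of their group in 6 of 182 groups of values examined (63 genes, 24 lists and 4 library measures, in each group), where a chance of 1 in 20 gives 9.1. Most of these genes were named for their small p-values, which favours tight groups, so that rate need not hold for them. DOX 3 held 39358457 counts against 14256948 to 20469533 in the other DOX tumours. DOX 2 had the highest Tube1 (18.9 CPM, others up to 16.1) and Shmt2 (145 CPM, others up to 124) of its group. DOX 4 had the lowest Smad5 of its group, 103 CPM against at least 114. No_DOX 3 had less Mcm6 than the other controls (116 CPM against at least 164) and the highest level of epithelial junction genes (0.24 on the centred log2 scale, the others no higher than -0.09).

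More genes differed between the groups at an unadjusted p under 0.05 than other groupings of these tumours usually gave. Of 100 splits, 3 reached 2592 genes, the real one included, the highest other split giving 2756. That lies under the share of 0.05 set in advance as the bound for chance, but not all 126 splits were run. The share was also not adjusted over the other results split this way, so it does not exclude chance for this count. That other split exchanged no_DOX 5 and DOX 2, and the real split gave 3462 genes without DOX 2, 1730 without no_DOX 4 and 1384 without both no_DOX 4 and DOX 5. Splits say nothing about edgeR's count of 0 genes at an adjusted p under 0.05, since 100 of 100 must give as many (highest other 1), and none were run for voom's 775, while for DESeq2's 322 chance is not excluded, with 2 of 40 splits reaching it and 500 as the highest other. A real difference of small size spread over many genes may lie behind the first count, and whether it comes from hepsin or from doxycycline was not testable in this design.

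The TGF-beta targets were higher with doxycycline, but 23 of 100 splits gave a camera p as small (real -log10 p 3.79, highest other 11.9), so chance cannot be excluded. With the basal marker level as a covariate the group difference in the list's mean was 0.089 (SE 0.12), against 0.25 (SE 0.20) without it, which is below the bound set for an explanation by more basal-type epithelium, with an error that reaches past that bound. More fibroblasts were not seen, as the fibroblast marker level was 0.08 ± 0.55 in controls and -0.08 ± 0.64 with doxycycline (SD, exact permutation p = 0.714). With that level as a covariate the difference was 0.32 (SE 0.08). A covariate that is lower with doxycycline and rises with the targets can only enlarge the difference. That fit therefore could not test for more fibroblasts, and the spread of the level leaves a small difference in fibroblasts open. From the fit with basal markers, a larger share of basal-type cells in some tumours remains a candidate explanation, beside a response to hepsin. The 2 are not exclusive since basal cells themselves can carry TGF-beta target transcripts. Of 4 lists past the threshold, 88 of 100 splits gave as many, with a highest other of 19, which points to lists that vary together between tumours whatever the grouping.

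The lower cell cycle and Myc target genes had camera p-values matched by 14 and 13 of 100 splits (real -log10 p 8.18 and 7.09, highest others 23.7 and 16.7), and the matrix list by 49 (real 2.16, highest other 20.7), so chance cannot be excluded for any of them. A different share of ribosomal and non-coding reads is only weakly argued against for the cell cycle and Myc targets. With that share as a covariate their joint difference was -0.23 (SE 0.10), against -0.22 (SE 0.09) without it, and its error came near the bound set in advance. With Myc transcript as a covariate the difference was -0.20 (SE 0.10), within 1 SE of the bound, so a part played by less Myc stays open. A list of 34 ribosome biogenesis genes outside the Myc targets was lower in 33, with a difference of -0.16 (SE 0.08) and an exact permutation p of 0.0714. That p is on the side set to count against a wider shift. With a tumour left out it ran from 0.0238 (without DOX 2) to 0.175, which leaves it open. A small fall in growth in doxycycline tumours is a hypothesis that these values may reflect, and a difference in the cell mixture was not excluded.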

How the results depend on the processing

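The alternatives without ribosomal loci, without both tumours at the ends of the first principal component (no_DOX 4 and DOX 5) and with permuted list means were chosen after the data were seen, and the others before; causes were not tested unless named. The count of genes past the threshold was 0 with edgeR under other scalings, filters, the robust fit and a threshold of 0.1, 322 with DESeq2, 775 with voom, and 0 to 37 when a library was left out (37 without no_DOX 3, 2 without DOX 2); unadjusted counts ran from 1384 to 4394. With library size only the share of genes at an unadjusted p under 0.05 that were higher was 67.8% against 51.2%, and with DESeq2 size factors 53.2%. Same-numbered tumours correlated weakly (0.0706 to 0.264) and only 3 of 10 correlated best with their own number, so the tumours were taken to share only a number; the replicate block gave 7 genes with edgeR, Col1a1, Col1a2 and Col3a1 among them, and 6 lists, adding basal markers (adjusted p = 0.00174) and TGF-beta components (0.0453), and for Hpn a difference of 0.52 with a smallest possible exact p of 0.0625. Hpn kept its direction throughout, at 0.32 with voom (limma p = 0.0594), 0.41 without both ends (exact p = 0.0571) and 0.38 to 0.60 when a library was left out. TGF-beta targets passed under every scaling, filter and left-out library (adjusted p 5.96e-05 to 0.0254), and not without both ends (0.162), with an estimated correlation (0.863), with fry (0.655) or with permuted list means (0.749). The matrix list ran from 0.000116 to 0.351, Myc targets from 7.25e-09 to 0.000153 and the cell cycle from 4.26e-13 to 4.93e-05 when a library was left out. With an estimated correlation all were at 0.863, with permuted means at 0.749, and with fry at 0.699 for matrix and 0.655 for Myc targets and cell cycle. Lists past the threshold numbered 7 without a filter, 7 without both ends, 3 to 7 when a library was left out, and 0 with an estimated correlation, fry or permuted means. Directions of some lists reversed, given as adjusted p. These were interferon with library size only (0.843), adipocyte (0.193) and neutrophil (0.722) without a filter, neutrophil at 1 CPM or more (0.995) and adipocyte with permuted means (0.749). Without both ends they were basement membrane (0.702), epithelial-mesenchymal transition (0.0965), hypoxia (0.595), interferon (0.00845), mitochondrial genes (0.555), squamous (0.802), adipocyte (0.474) and neutrophil (0.555). With a library left out, at least once each, they were interferon (adjusted p over the left-out libraries 0.0343 to 0.934), neutrophil (0.331 to 0.977), fibroblast (0.0750 to 0.964), epithelial-mesenchymal transition (0.10 to 0.848) and adipocyte (0.376 to 0.934). Of 1253 values of the 63 named genes under other settings, 1178 stayed on the same side of the threshold and in the same direction and 72 moved past it. Isg15 reversed with voom (-0.22) and without both ends (-0.014), and Ltf with voom (0.060). At these depths genes with few counts, such as Rnase2a, remain the least certain.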

Other observations

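The lists of cell types and pathways tested here were picked after genes of each had been seen among the smallest p-values, before the level of the list itself was computed. An exact p of 0.05 or more had been set in advance to count against each of them. Once the values were seen, this was applied only where the p stayed at 0.05 or more with each tumour left out in turn, lists with under 5 tested genes were left undecided, and the comparison with the size of the Foxj1 difference was added. Serine and one-carbon synthesis genes were lower with doxycycline beyond Psat1 and Shmt2, which were left out of the list. Of its 14 genes, 13 were lower and 7 had an unadjusted p under 0.05, with a median log2 fold change of -0.23. Shmt1, the cytosolic counterpart of Shmt2, had a log2 fold change of -0.35, the glutamine and serine carrier gene Slc1a5 -0.38 and Phgdh, the entry enzyme of serine synthesis, -0.30. The list also holds the purine synthesis genes Pfas, Paics, Atic and Gart, at -0.27, -0.14, -0.15 and -0.12. The mean level was 0.10 ± 0.09 in controls and -0.10 ± 0.10 with doxycycline (SD, n = 5), with 4 of 5 DOX tumours below every control. The exact permutation p was 0.0238, or 0.0476 adjusted over the 4 lists picked after the data were seen. The adjusted value rests on the smaller p of the eosinophil list, which does not count as support, as given below. Without that list it would not stay under 0.05. The exact p was also not adjusted over the 24 lists tested before, so it is weaker evidence than it looks. Lower serine and one-carbon synthesis in doxycycline tumours is a hypothesis from these values. It overlaps with the lower Myc targets and was not separated from them.

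Rnase2a and Ear2, ribonucleases known from eosinophils and some macrophages, had log2 fold changes of 4.83 and 3.07 with doxycycline, on summed counts of 5 and 15 in controls and 168 and 156 in DOX tumours. A list of 15 other eosinophil genes had only 3 members with enough counts to test (Ccl24, Ccl11 and Alox15), with log2 fold changes of 4.97, 1.09 and 0.65. Their mean was higher in 5 of 5 DOX tumours than in any control (exact permutation p = 0.00794, the smallest the design allows). The low-count filter kept Ccl24 only through the DOX tumours, and dropped Siglecf (9 counts in controls and 15 with doxycycline) and Ccr3 (6 and 15). This p therefore does not count as support for more eosinophils. Ccl24, at 8 counts in controls and 277 with doxycycline, and Ccl11, at 81 and 187, encode chemokines that attract eosinophils, and other cells make them. The granule protein genes Prg2 and Epx had summed counts of 1 and 0 over all 10 tumours, and Siglecf had 24. More eosinophils may be present, but with 3 genes, 2 of them chemokines, this cannot be told apart from a change in the cells that make Ccl24, or in macrophages. The macrophage markers Cd163 and Mrc1 had log2 fold changes of 1.41 and 0.65 (edgeR adjusted p of 0.239 and 0.2695). Their list had 12 members higher and 5 lower, with a median of 0.05.

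Multiciliated cell genes were not higher as a set by as much as Foxj1. Of 30 such genes other than Foxj1 and Stk36, 8 had enough counts, 5 higher and 3 lower, and 3 had an unadjusted p under 0.05 with edgeR (log2 fold changes of 0.51 for Rfx2, 0.97 for Tekt2 and -0.45 for Rsph1). Their mean level differed by 0.13 (SE 0.11), against 2.17 (SE 0.30) for Foxj1. The exact permutation p of 0.310 lay on the side set to count against any wider difference. With a tumour left out it ran from 0.0397 (without DOX 2) to 0.460, so a small difference was neither shown nor excluded. For Hpn, more luminal epithelium with doxycycline is only weakly argued against as its source. With the luminal marker level as a covariate the log2 difference was 0.57 (SE 0.27), against 0.54 (SE 0.22) without it. Its error nearly reached the bound set in advance for that explanation.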
